A study of Homo sapiens with 12 samples.

How the data were processed

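RNA of the human mantle cell lymphoma lines Mino, Rec-1 and SP-49 was measured on 12 Affymetrix arrays of 54675 probe sets. Each line had 2 arrays after 24 h with 1 µM compound E and 2 after 24 h with 0.1% DMSO, with 15% serum for Mino and 10% for Rec-1 and SP-49. The deposited values were on the log2 scale and normalized between arrays by the authors, who named RMA and limma as processing tools without versions. Base 2 was inferred from the values, which ran from 0.58 to 12.78 with a median of 1.99. Values near the bottom of this range are dominated by background, so a fall that ends there is understated. The number of arrays, 2 per group, limits the precision, and the median standard error of a change in 1 line was 0.164. Scan dates and batches are not given in the sources used here, nor is it given whether replicates were separate cultures.

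Of the probe sets, 41097 named 1 gene, 1801 named several genes and 11777 had no gene name in the annotation used here. Symbols were brought to current names by gene number for 41043. A gene was represented by the probe set with the highest mean over all arrays among those that named that gene alone, which gave 19775 genes, 10523 of them with several probe sets to choose from. No gene was removed for a low value, and 5377 genes had a highest group mean under the median probe set.

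Changes were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance). The model had 6 group means over all 12 arrays, with 6 residual and 5.22 prior degrees of freedom. The contrasts were inhibitor minus mock in each line, the average of these, their differences between lines, and the differences between lines in the mock arrays. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 19775 genes within each contrast, with a threshold of 0.05. Intervals of 95% are those of limma for a single gene, not adjusted for the number of genes.

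Gene lists, 30 in number with 675 genes, were written from textbook knowledge. They covered Notch targets, Notch-linked B-cell genes, Notch machinery, MYC-linked ribosome biogenesis and metabolism, G1/S and G2/M, B-cell receptor signalling, B-cell identity, plasma cells, germinal centre, mantle cell lymphoma markers, NF-kB, apoptosis, p53, MHC class II, interferon, cholesterol, ATF4 stress, hypoxia and glycolysis, immediate-early genes, heat shock, ribosomal proteins, chemokines and migration, and markers of 6 other cell types. Each was tested against all other genes with camera at a preset correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the 30 lists. The test was repeated with the correlation estimated per list and with fry, a self-contained test. List members that could not be matched to a gene here were not analysed here. Coverage was under 80% of the members for the cholesterol, heat-shock, ribosomal protein and red-cell lists.

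Genes were named by a rule. For each line, the rule took members of the lists of Notch targets and Notch-linked B-cell genes past the threshold in any line, and HES1, HES4, HEY1, DTX1, NRARP, NOTCH1, NOTCH3 and MYC whatever their p. It added the 10 largest rises and the 10 largest falls past the threshold with both inhibitor arrays beyond both mock arrays, and up to 4 members with the smallest adjusted p of each list that passed camera. For the average, it took the 5 largest each way that moved in 1 direction in all 3 lines. For differences between lines it took the 5 largest each way, and for the mock arrays the 5 genes per line that stood furthest above both other lines. Values of other genes named by this rule in 1 comparison were also given in other comparisons.

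The model, the threshold, the lists, the naming rule and the alternatives, except the 2 named as added later, were chosen before the data were examined. The alternatives were every probe set tested on its own, the mean of a gene's probe sets, dim genes left out, quantile normalization applied again, median centring, an intensity trend with a robust prior, only the arrays compared, a minimum of 1.5-fold, a replicate block, and each array left out in turn. When 1 array was left out, the remaining array of its group was assumed to vary like the others. Array weights, and both doubted arrays left out together, were added after the data were seen. The doubted arrays were inhibitor replicate 2 of Rec-1 and of SP-49, which had the narrowest signal ranges (SD 1.95 and 2.00 over probe sets).

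The pipeline was tested on simulated data with the same layout, with independent normal noise of equal spread in all groups. It recovered 88.1%, 85.1% and 89.6% of genes changed by 1 log2 unit in Mino, Rec-1 and SP-49, 10.4%, 9.0% and 16.4% of genes changed by 0.5, and 100% of genes changed by 2, with 6, 8 and 12 false calls. Of the simulated lists, the lowered list was called (adjusted p = 2.05e-29) and 1 unchanged list was called. In the real arrays the SD of the replicate difference ran from 0.206 (SP-49 mock) to 0.372 (Rec-1 inhibitor), so the simulated rates need not hold there. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.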

Results

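Gene expression was measured on Affymetrix arrays in Mino, Rec-1 and SP-49, 3 cultured human lines of mantle cell lymphoma, a B-cell cancer. Each line was kept for 24 h with 1 µM compound E, a gamma-secretase inhibitor that blocks the cleavage by which Notch receptors become active, or with 0.1% DMSO alone (mock). The 12 arrays formed 6 groups of 2, and their number limits the precision of every value. Mino was grown in 15% serum and the other lines in 10%, so the serum level went with the line. The comparisons asked which transcripts change when gamma-secretase is blocked in each line, and whether the lines respond differently. Arrays of 1 line correlated across probe sets with r from 0.979 to 0.995, and arrays of different lines with r from 0.932 to 0.953. The difference between the 3' and 5' control probe sets of GAPDH, a sign of RNA quality, was higher on both inhibitor arrays than on both mock arrays in Rec-1 (0.59 and 0.49 against 0.41 and 0.37) and in Mino (0.31 and 0.39 against 0.26 and 0.25). In SP-49 it overlapped (0.35 and 0.44 against 0.35 and 0.34), and that of ACTB overlapped in Rec-1 and SP-49 and was higher with inhibitor in Mino (at least 1.94 against at most 1.79). Changes are differences of log2 values, inhibitor minus mock, and levels are means on the log2 scale ± SD (n = 2). The p-values measure only the spread between these samples, which may be technical.

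In Rec-1, the inhibitor lowered the classical Notch target genes. HES1, a repressor that Notch switches on directly, fell by 3.80 on the log2 scale (95% interval -4.23 to -3.38), at least 14-fold lower, from 5.77 ± 0.14 to 1.96 ± 0.37 (n = 2), which is near the low end of the arrays' range. The related repressors HEY1 and HES4 were 7.68-fold and 5.56-fold lower, and NRARP, a feedback inhibitor of Notch, was 2.61-fold lower. MYC, the growth regulator, fell by 1.54 (95% interval -1.92 to -1.15), 2.9-fold lower, from 8.35 ± 0.04 to 6.82 ± 0.42 (n = 2). The interval uses a spread shared by all 6 groups and may be too narrow here. With 1 array left out, the MYC change ran from -1.83 to -1.24. The surface receptors FCRL4 and CR2 of B cells were 9.69-fold and 8.82-fold lower, and both inhibitor arrays lay below both mock arrays for each of these genes. Of 3 probe sets that name HES1, the other 2 had weaker changes in Rec-1, up to 0.23, and neither rose past the threshold.

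Of 14 direct Notch targets measured, 7 fell and none rose in Rec-1 (8 fell when adjusted over the list alone), with a median change of -0.68 (camera adjusted p = 3.38e-06; adjusted p = 0.0179 with an estimated correlation). The receptor gene NOTCH3 fell by 0.93 (adjusted p = 0.00466; 0.0529 without mock replicate 2 of Rec-1), while NOTCH1 itself had a change of 0.17 (adjusted p = 0.474). DTX1, another Notch target, had a change of -0.50 (adjusted p = 0.0371), and its adjusted p reached 0.2 without mock replicate 1 of Rec-1. Of 16 genes tied to Notch in B cells, 6 fell, also when adjusted over the list alone, with a median of -0.25 (adjusted p = 0.000104; adjusted p = 0.088 with an estimated correlation). Among them, CD300A, an inhibitory receptor, fell by 1.54, the adaptor SH2B2 by 1.00 and the kinase FYN by 0.93.

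**Figure D1:**
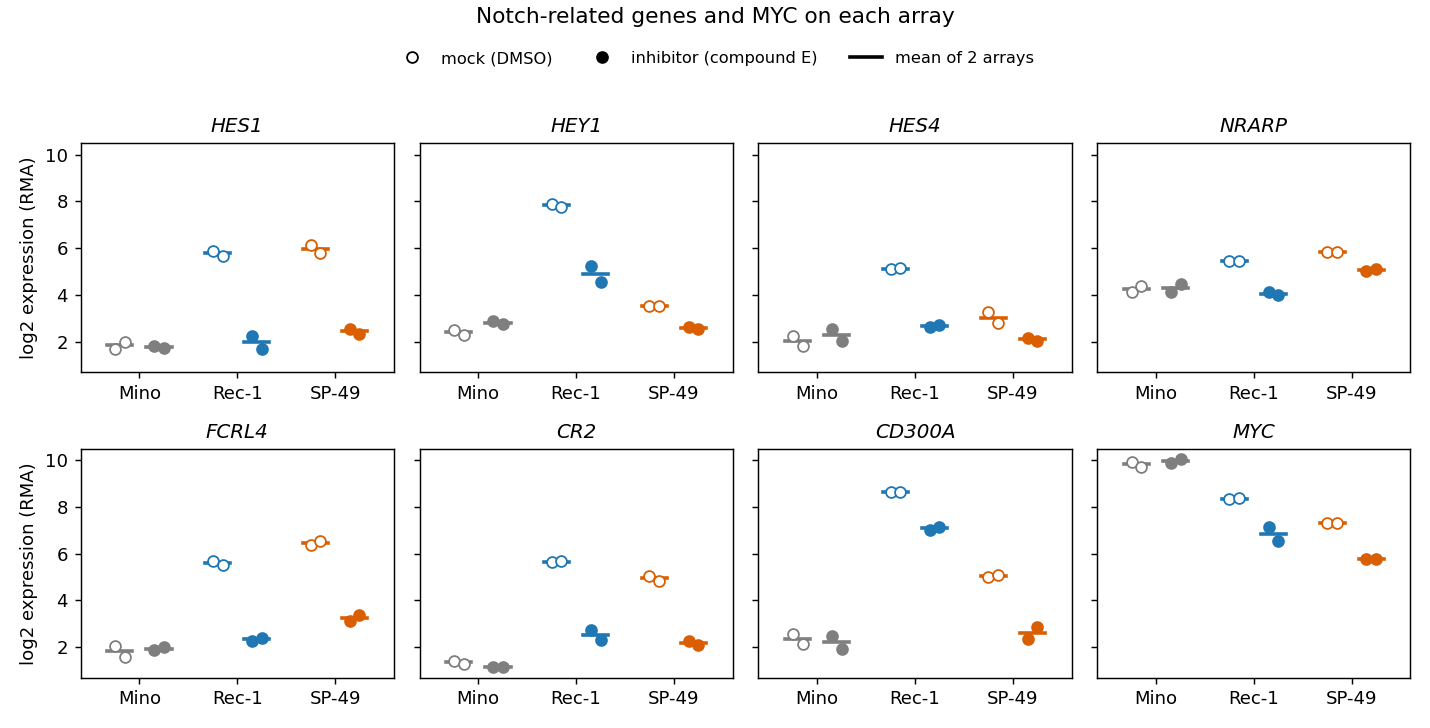
Log2 array value (vertical axes) of 8 genes in each line without (open symbols) and with (filled symbols) the inhibitor; each symbol is 1 array and each bar the mean of 2. HES1 went from 5.77 to 1.96 in Rec-1 and from 5.94 to 2.43 in SP-49, and had means of 1.84 and 1.77 in Mino.

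Genes of cell growth that MYC is known to drive fell together in Rec-1. Of 34 measured genes of ribosome biogenesis, 27 fell (34 when adjusted over the list alone), with a median of -0.94 (adjusted p = 1.23e-35; adjusted p = 0.00214 with an estimated correlation). RRP12, TSR1, NOP16 and LYAR, which act in the nucleolus, fell by 1.55, 1.46, 1.44 and 1.26. Of 31 MYC-linked metabolic genes, 24 fell (25 when adjusted over the list alone), with a median of -0.71 (adjusted p = 1.56e-22; adjusted p = 0.0027 with an estimated correlation). HK2, a hexokinase that starts glycolysis, fell by 1.91, and SRM, which makes spermidine, by 1.39. Of 14 heat-shock genes, 7 fell (9 when adjusted over the list alone), with a median of -0.47 (adjusted p = 2.25e-07; adjusted p = 0.0179 with an estimated correlation). The chaperone FKBP4 was 2.84-fold lower, and the chaperone HSP90AB1 fell by 0.75. Of 29 genes of hypoxia and glycolysis, 6 fell and 1 rose, also when adjusted over the list alone, with a median of -0.29 (adjusted p = 0.000241; adjusted p = 0.115 with an estimated correlation). VEGFA, the vessel growth factor, fell by 1.15. The 3' to 5' difference of GAPDH was higher on the same inhibitor arrays (0.59 and 0.49 against 0.41 and 0.37).

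Interferon-response genes rose in Rec-1. Of 31 measured, 11 rose and 1 fell (19 and 2 when adjusted over the list alone), with a median of 0.63 (adjusted p = 1.18e-13; adjusted p = 0.0441 with an estimated correlation). The antiviral genes MX1, ISG15, IFITM1 and IFI44L rose by 1.69, 1.83, 1.66 and 1.63, and IRF9, a factor that carries the interferon signal to the nucleus, rose by 1.24. The member that fell was CXCL10, a chemokine, by 2.32, from 6.40 ± 0.08 to 4.08 ± 0.93 (n = 2). SAMD9L and CMPK2, with rises of 2.17 and 1.85, are further genes known to respond to interferon. These rises went with the higher 3' to 5' difference of GAPDH on the Rec-1 inhibitor arrays (0.59 and 0.49 against 0.41 and 0.37).

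Some genes of B-cell identity and signalling rose in Rec-1, and both lists passed at the preset but not at an estimated correlation. Of 28 genes of B-cell receptor signalling, 8 rose and 1 fell (13 and 1 when adjusted over the list alone), with a median of 0.24 (adjusted p = 0.000689; adjusted p = 0.0936 with an estimated correlation). CD79B, a signalling chain of the receptor, rose by 1.06 and the adaptor DAPP1 by 0.94. Of 23 B-cell identity genes, 5 rose (7 rose and 1 fell when adjusted over the list alone), with a median of 0.34 (adjusted p = 0.000941; adjusted p = 0.157 with an estimated correlation). ID3, an inhibitor of E-protein transcription factors, rose by 0.90. Of 28 immediate-early genes, 6 rose, also when adjusted over the list alone, with a median of 0.23 (adjusted p = 0.000282; adjusted p = 0.0475 with an estimated correlation), among them KLF2, a factor of lymphocyte quiescence, by 1.42. Of 27 NF-kB targets, 4 rose, also when adjusted over the list alone, with a median of 0.30 (adjusted p = 0.00174; adjusted p = 0.137 with an estimated correlation). CFLAR, an inhibitor of caspase-8 activation, was the NF-kB target with the smallest adjusted p (0.00466) and rose by 0.82. Its adjusted p was 0.0531 without mock replicate 1 of Rec-1. Of 23 genes of chemokine signalling and migration, 6 rose and 1 fell (9 and 2 when adjusted over the list alone), with a median of 0.16 (adjusted p = 0.00619; adjusted p = 0.115 with an estimated correlation). GPR183, which positions B cells in follicles, rose by 1.19 and the tetraspanin CD9 by 1.05. All of these lists moved on arrays with a higher 3' to 5' difference of GAPDH (0.59 and 0.49 against 0.41 and 0.37).

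Of 32 genes of the G2 and M phases, 1 rose in Rec-1, also when adjusted over the list alone, with a median of 0.10 (adjusted p = 0.0289; adjusted p = 0.417 with an estimated correlation). That gene, HMMR, had a change of 0.50 (adjusted p = 0.034), and its adjusted p reached 0.182 without mock replicate 2 of Rec-1. The G1/S list had a median of -0.05 (adjusted p = 0.454). Markers of T cells, NK cells, myeloid cells, stroma, epithelium and red cells, in 6 lists, had medians from -0.07 to 0.08 in Rec-1 (smallest adjusted p = 0.107).

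The 10 largest rises in Rec-1 by the naming rule were led by MTSS1, a membrane and actin regulator, at 5.32-fold (from 4.12 ± 0.09 to 6.53 ± 0.33, n = 2; adjusted p = 4.42e-05). C16orf54, RNASE6, the immunoglobulin heavy chain (IGH), the lipid-presenting molecule CD1C, MPEG1 and MARCHF1 rose by 2.36, 2.33, 2.15, 2.09, 1.86 and 1.84. Besides HES1, HEY1, HES4, FCRL4, CR2 and CXCL10, the 10 largest falls by the rule included the nucleotide receptor P2RY2 (2.63), KAZN (2.27), SP3P (2.06) and TSPAN11 (1.97), each value being the size of a fall on the log2 scale. SP3P is named as a pseudogene of SP3, and its probe set was not tested for signal from SP3.

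Across all 19775 genes, 1141 passed an adjusted p of 0.05 in Rec-1, 426 higher and 715 lower, and 942 of them changed at least 1.5-fold. The division between higher and lower depended on the scaling and on 1 array, with 657 higher and 600 lower after quantile normalization was applied again and 372 higher and 366 lower without inhibitor replicate 2 of Rec-1. The count was 426 without mock replicate 1 of Rec-1, 414 without mock replicate 2, 1997 without inhibitor replicate 1, 738 without inhibitor replicate 2, and 21 when only the 4 Rec-1 arrays were fitted.

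In SP-49, fewer genes passed, and the largest falls by the naming rule were in HES1, FCRL4, CR2, CDK5R1 and CD300A. HES1 fell by 3.51, 11.4-fold lower, from 5.94 ± 0.24 to 2.43 ± 0.15 (n = 2; adjusted p = 1.18e-05). FCRL4 was 9.28-fold lower, CR2 6.73-fold, CDK5R1, an activator of the kinase CDK5, 6.26-fold, and CD300A 5.4-fold. MYC fell by 1.55, 2.93-fold lower, from 7.32 ± 0.01 to 5.77 ± 0.03 (n = 2). BIK, which promotes apoptosis, was 3.08-fold higher (adjusted p = 0.00161).

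HEY1, HES4 and NRARP had changes of -0.95, -0.93 and -0.76 in SP-49 (adjusted p = 0.107, 0.132 and 0.0756). Of the 14 Notch targets, 2 fell (5 fell and 1 rose when adjusted over the list alone), with a median of -0.17 (adjusted p = 0.00173; adjusted p = 0.0505 with an estimated correlation). Of the 16 Notch-linked B-cell genes, 5 fell (7 when adjusted over the list alone), with a median of -0.37 (adjusted p = 5.62e-09; adjusted p = 0.0292 with an estimated correlation). Both lists fell more on inhibitor replicate 2 of SP-49, a doubted array, than on replicate 1. Against the mock mean, the medians on replicates 1 and 2 were -0.063 and -0.285 for Notch targets and -0.258 and -0.592 for Notch-linked B-cell genes. Of 34 ribosome biogenesis genes, none passed over all genes and 19 fell when adjusted over the list alone, with a median of -0.41 (adjusted p = 5.64e-17; adjusted p = 0.00851 with an estimated correlation). WDR43, the member with the smallest adjusted p (0.0714), had a change of -0.80. Of 31 MYC-linked metabolic genes, 1 fell (9 fell and 1 rose when adjusted over the list alone), with a median of -0.32 (adjusted p = 4.46e-08; adjusted p = 0.0292 with an estimated correlation). This gene, HK2, fell by 1.18 and was also the only gene that passed of 29 in the hypoxia and glycolysis list, of which 2 fell when adjusted over the list alone. The median of that list was -0.17 (adjusted p = 0.00263; adjusted p = 0.223 with an estimated correlation).

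Plasma-cell genes rose as a group in SP-49. Of 16 measured, 1 passed over all genes and 3 rose when adjusted over the list alone, with a median of 0.36 (adjusted p = 5.62e-09; adjusted p = 0.00851 with an estimated correlation). MZB1, an endoplasmic reticulum protein of antibody secretion, rose by 0.80 (adjusted p = 0.0463), and JCHAIN, which joins secreted antibodies, had a change of 0.60. Ribosomal protein genes had a median of -0.09, with 0 of 31 past the threshold by limma over all genes and 0 when adjusted over the list alone (adjusted p = 0.016; adjusted p = 0.504 with an estimated correlation). Cholesterol genes had a median of 0.08, with 0 of 20 past the threshold and 1 higher when adjusted over the list alone (adjusted p = 0.045; adjusted p = 0.169 with an estimated correlation). The interferon list had a median of -0.11 in SP-49 (adjusted p = 0.126), and the 6 lists of other cell types had medians from -0.11 to 0.08 (smallest adjusted p = 0.161).

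In all, 38 genes passed in SP-49, 4 higher and 34 lower. The higher genes were BIK, RASSF6 (1.11), PITPNM2 (0.90) and MZB1 (0.80), with log2 changes in brackets. LAMP3, CDH1, GPAT3, ETV1 and IL6R fell by 1.89, 1.73, 1.72, 1.45 and 1.22. The count ranged from 7 without mock replicate 1 of SP-49 to 72 without 1 inhibitor array of Rec-1, whichever it was, and leaving out any of the 12 arrays moved it by over 1.5 times. It was 11 when only the 4 SP-49 arrays were fitted. The calls of HES1, FCRL4, CR2, CDK5R1, CD300A and BIK held without any 1 array, while the adjusted p of MYC reached 0.0885 without inhibitor replicate 2 of SP-49 and that of HK2 0.171, and those of the other genes named here as passing reached between 0.116 (ETV1) and 0.393 (MZB1).

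In Mino, HES1 was at the low end of the range with and without inhibitor, at 1.77 ± 0.06 and 1.84 ± 0.22 (n = 2). MYC was high in both groups, at 9.95 ± 0.13 with and 9.82 ± 0.14 without inhibitor (n = 2). NRARP, HEY1, HES4, CR2 and FCRL4 had changes of 0.06, 0.42, 0.26, -0.21 and 0.11. By limma, 0 genes passed (smallest adjusted p = 0.355), and 969 of 19775, or 4.9%, had an unadjusted p under 0.05. With an intensity trend and robust prior in limma, 1 gene passed. Of the 30 gene lists, 0 passed with camera at the preset correlation, 0 with an estimated correlation and 0 with fry, and 3 passed with camera without mock replicate 2 of Mino.

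**Figure D2:**
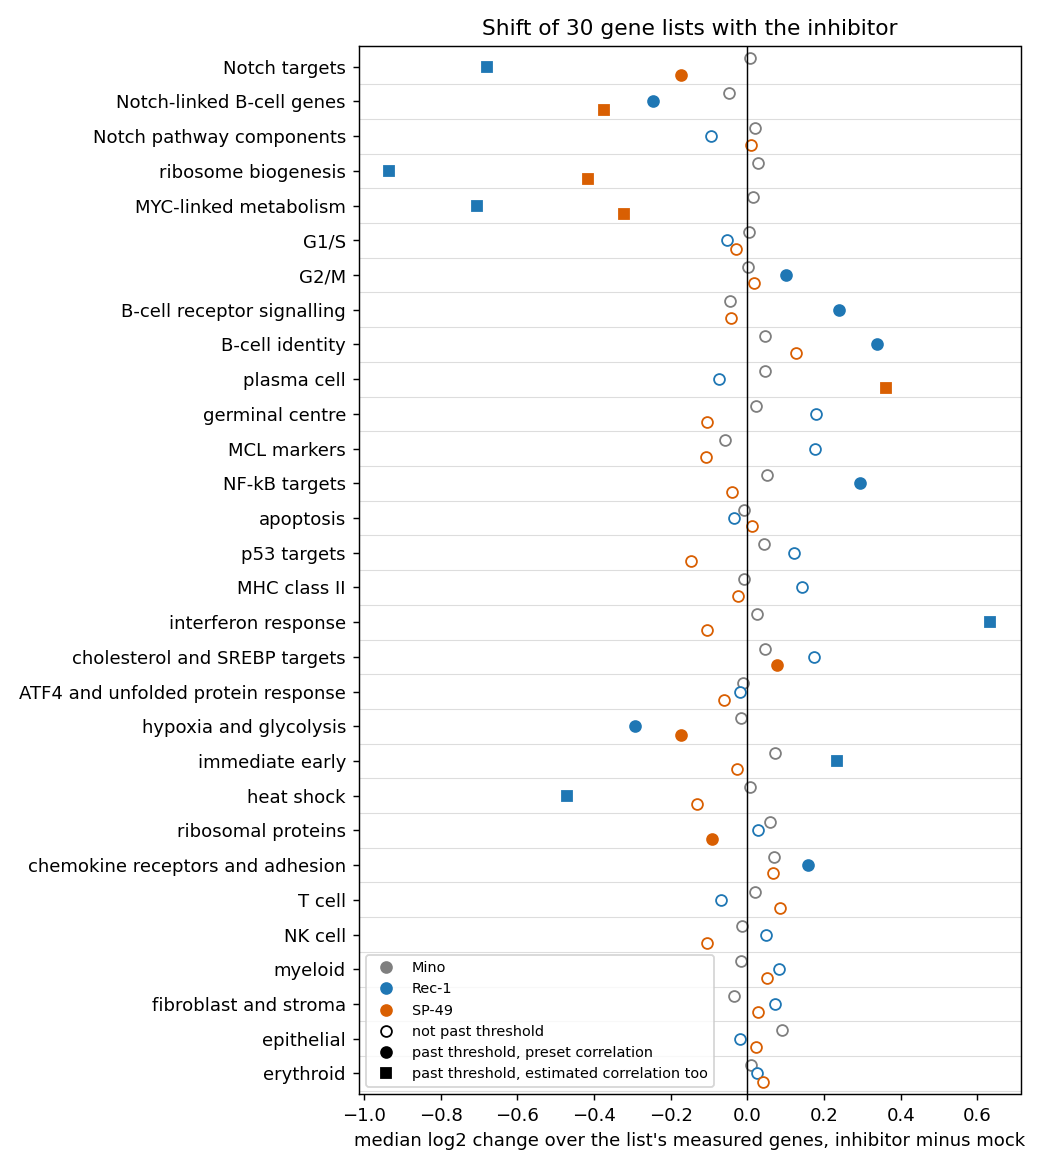
Median log2 change, inhibitor minus mock (horizontal axis), of the 30 gene lists in each line; open circles did not pass camera, filled circles passed with the preset correlation and squares also with an estimated correlation. Ribosome biogenesis genes had medians of -0.94 in Rec-1 and -0.41 in SP-49, and interferon genes a median of 0.63 in Rec-1.

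The falls in Rec-1 and SP-49 overlapped. Of 715 genes that fell in Rec-1 and 34 that fell in SP-49, 16 were shared, where 1.23 would be expected of independent sets (Fisher's exact test, two-sided, p = 8.69e-15), and 2 of the higher genes were shared (p = 0.0027). Genes are not independent replicates, so these p-values describe overlap across genes only. Both lines also share 1 estimate of each gene's spread, so a gene with a small estimate is likelier to pass in both. Some overlap beyond the expected number can come from that. All 18 shared genes changed in the same direction, among them HES1, FCRL4, CR2, CD300A, MYC, HK2, FYN, CDK5R1, BIK and RASSF6. In Rec-1 the adjusted p of CDK5R1 reached 0.134 without mock replicate 2 of that line and that of BIK 0.14 without mock replicate 1. In SP-49 the call of FYN (adjusted p = 0.045) ended in 10 of the 12 fits that left out 1 array, reaching 0.393 without mock replicate 1, and the calls of MYC, HK2 and RASSF6 ended in 3, 3 and 4 of them, reaching 0.0885, 0.171 and 0.238. Of the 715 genes, 615 (86%) also had a negative change in SP-49, with a median of -0.26 (camera adjusted p = 2.09e-30; adjusted p = 0.037 with an estimated correlation). The median change of all genes in SP-49 was -0.019. Of the 426 genes that rose in Rec-1, 251 (58.9%) had a positive change in SP-49, with a median of 0.051 (camera adjusted p = 0.00014; adjusted p = 0.129 with an estimated correlation). Neither set was tested against genes of like brightness or without the doubted arrays, so a shared compression of the signal range stays open. In Mino the median change of the 715 genes was 0. Across genes, the changes correlated with r = 0.278 (Spearman 0.216) between Rec-1 and SP-49, -0.025 between Rec-1 and Mino, and -0.045 between SP-49 and Mino. Without inhibitor replicate 2 of Rec-1, r was 0.147 between Rec-1 and SP-49 and 0.02 between Rec-1 and Mino. With 1 array left out, r ranged from -0.057 (without inhibitor replicate 1 of Rec-1) to that value for Rec-1 and Mino, and from -0.063 to -0.007 (without inhibitor replicates 1 and 2 of SP-49) for SP-49 and Mino.

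**Figure D3:**
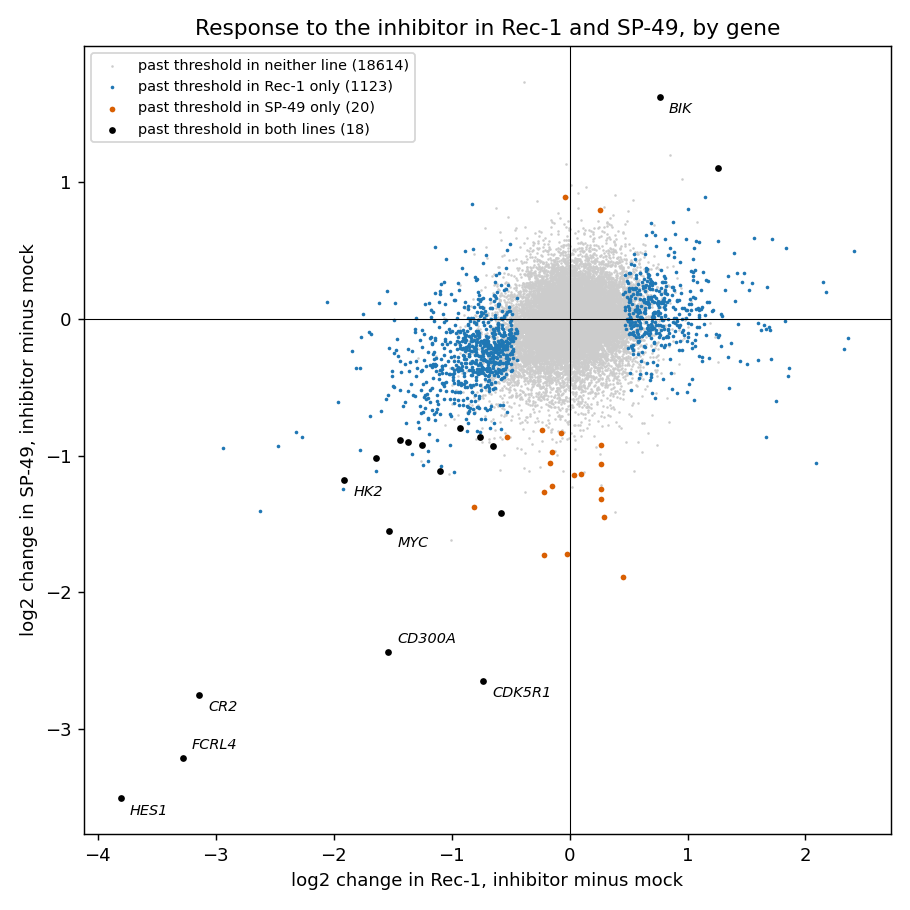
Log2 change in Rec-1 (horizontal axis) against that in SP-49 (vertical axis), 1 point per gene, coloured by where the gene passed an adjusted p of 0.05. HES1, FCRL4 and CR2 lie at the lower left, with changes of -3.80, -3.28 and -3.14 in Rec-1 and -3.51, -3.22 and -2.75 in SP-49.

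The difference between lines was tested directly. Compared with Mino, Rec-1 had lower changes of HES1, FCRL4, HEY1 and CR2, with differences of -3.73, -3.39, -3.36 and -2.93 on the log2 scale. These genes had mock levels of 1.84, 1.82, 2.39 and 1.36 in Mino, at or near the low end of the range, so they had little room to fall there and the differences do not compare responses from like starting levels. MTSS1, RNASE6 and CD1C had higher changes in Rec-1 than in Mino, by 2.39, 2.36 and 2.11, and MYC differed by -1.67 (adjusted p = 0.0117; 0.0626 without inhibitor replicate 2 of Mino). The CD1C difference reached an adjusted p of 0.061 without that same array, and those of HES1, FCRL4, HEY1, CR2, MTSS1 and RNASE6 passed without any 1 array. In all, 283 genes differed, 111 with a higher and 172 with a lower change in Rec-1, and these numbers were 152 and 134 after repeated quantile normalization, 81 and 211 after median centring and 124 and 109 without inhibitor replicate 2 of Rec-1. The count ranged from 53 without inhibitor replicate 2 of Mino to 940 without inhibitor replicate 1 of Rec-1.

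SP-49 differed from Mino in 9 genes, 1 with a higher and 8 with a lower change. HES1, FCRL4, CR2 and CDK5R1 differed by -3.44, -3.32, -2.54 and -2.48, and these calls held without any 1 array. The mock levels of CDK5R1 and CD300A in Mino were 2.17 and 2.35, so the limit of little room to fall in Mino covers HES1, FCRL4, CR2, CDK5R1 and CD300A. CD300A differed by -2.28 and BIK by 1.80, with adjusted p up to 0.235 without mock replicate 1 of SP-49 and 0.166 without inhibitor replicate 1 of Mino. For MYC the difference was -1.69 and did not pass (adjusted p = 0.0564). The count lay between 4 without mock replicate 2 of Mino and 13 without inhibitor replicate 1 of Rec-1.

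Between Rec-1 and SP-49, the changes differed in interferon genes, while no difference was detected in HES1 or MYC. The HES1 changes differed by -0.30 (95% interval -0.90 to 0.31, adjusted p = 0.77) and the MYC changes by 0.02 (95% interval -0.53 to 0.56, adjusted p = 0.991). HES1 ended near the low end of the range in both lines, which bounds both falls, so a difference in its response could be hidden. The changes of CD1C, RNASE6, IFIT3 and MX1 were higher in Rec-1 by 3.14, 2.55, 2.53 and 1.75. CD1C rose by 2.09 in Rec-1 and had a change of -1.05 in SP-49 (adjusted p = 0.111). HEY1, HES4 and DTX1 had lower changes in Rec-1, by -1.99, -1.55 and -1.05 (adjusted p = 0.0156, 0.0482 and 0.0275), which reached 0.0911 without mock replicate 1 of SP-49, 0.217 without mock replicate 2 of SP-49 and 0.15 without mock replicate 1 of SP-49. HEY1 and HES4 had mock levels of only 3.53 and 3.02 in SP-49, against 7.83 and 5.12 in Rec-1, and ended at 2.58 and 2.09 there, near the low end of the range, so SP-49 had little room for a fall of the size seen in Rec-1. Among lists, the interferon change was higher in Rec-1 by a median of 0.79 (camera adjusted p = 4.89e-17; adjusted p = 0.040 with an estimated correlation), and that of plasma-cell genes was lower by -0.46 (adjusted p = 0.040 with an estimated correlation). As a list, interferon genes already stood higher in SP-49 than in Rec-1 without inhibitor. Their difference therefore does not compare responses from like starting levels. The ribosome biogenesis change differed by -0.48 (adjusted p = 0.0148 with an estimated correlation). In all, 110 genes differed, 76 higher and 34 lower in Rec-1, with a range from 6 without mock replicate 1 of SP-49 to 283 (108 higher and 175 lower) without inhibitor replicate 1 of Rec-1. The adjusted p of the RNASE6 difference was 0.0797 without mock replicate 1 of SP-49, while those of CD1C, IFIT3 and MX1 passed without any 1 array.

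**Figure D4:**
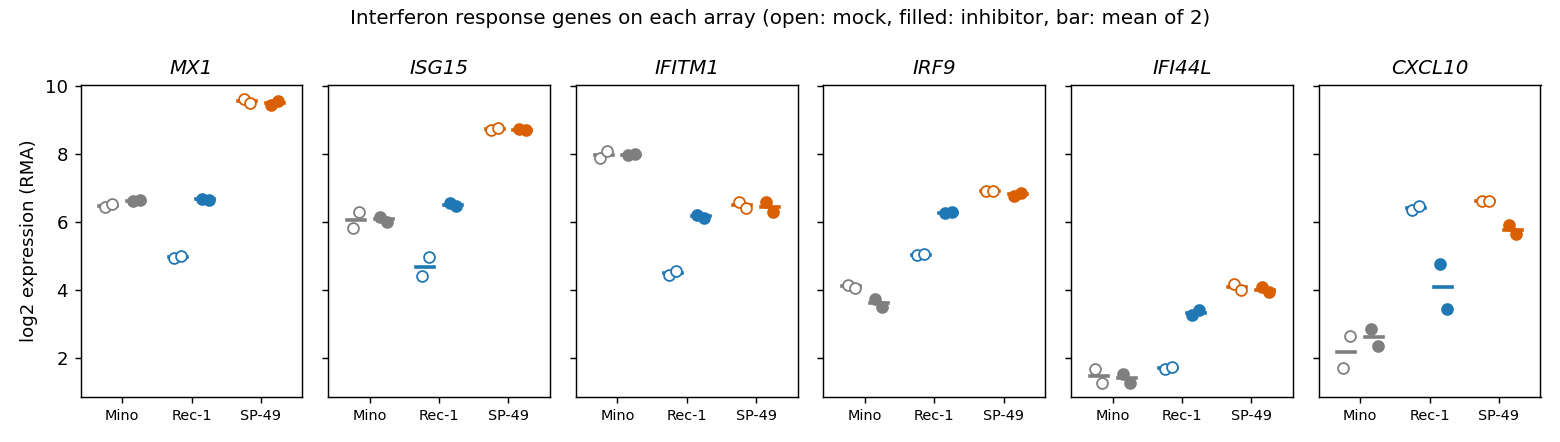
Log2 array value (vertical axes) of 6 interferon-response genes in each line without (open symbols) and with (filled symbols) the inhibitor; each symbol is 1 array and each bar the mean of 2. ISG15 went from 4.67 to 6.50 in Rec-1 and had means of 8.71 and 8.70 in SP-49, and CXCL10 fell from 6.40 to 4.08 in Rec-1.

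Averaged over the lines, HES1, CR2, P2RY2, CD300A and CDK5R1 had the largest falls among genes whose estimated changes had 1 sign in all 3 lines, by 2.46, 2.04, 1.39, 1.38 and 1.18. MTSS1, IGH, SAMD9L, RASSF6 and KLF2 had the largest rises, by 0.98, 0.92, 0.88, 0.81 and 0.77, and all 10 calls held without any 1 array. None of these genes passed in Mino, where the changes of HES1, MTSS1 and RASSF6 were -0.07, 0.02 and 0.05, and FCRL4, with an average change of -2.13, was left out for its change of 0.11 in Mino. In this average 376 genes passed, 101 higher and 275 lower, or 182 and 211 after repeated quantile normalization. Of the 30 lists, 13 passed, 7 up and 6 down, and 5 passed with an estimated correlation. The count of genes ranged from 105 without mock replicate 1 of SP-49 to 987 without inhibitor replicate 1 of Rec-1, and moved by over 1.5 times without any 1 array except inhibitor replicate 2 of Rec-1 and inhibitor replicate 1 of SP-49.

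Without inhibitor, the lines differed in HES1, MYC, antigen presentation and interferon-response genes. HES1 was at least 15.2-fold higher in Rec-1 and at least 17.1-fold higher in SP-49 than in Mino (adjusted p = 5.56e-08 and 4.73e-08), as bounds, since its level in Mino was under that of the median probe set. The list of Notch targets was higher in Rec-1 than in Mino, with a median of 0.66 (adjusted p = 0.000446; adjusted p = 0.0421 with an estimated correlation), and did not pass for SP-49 against Mino (median 0.45, adjusted p = 0.0811) or Rec-1 against SP-49 (median 0.23, adjusted p = 0.0536). MYC was lower in Rec-1 and SP-49 than in Mino, with differences of -1.47 and -2.50. Of 16 MHC class II genes, which present antigen to T cells, 12 were lower and 1 higher in Rec-1 than in Mino (13 and 1 when adjusted over the list alone), with a median of -2.14 (adjusted p = 9.71e-13; adjusted p = 0.00553 with an estimated correlation). As a list, interferon-response genes were highest in SP-49, with a median difference of 2.10 from Mino, where 25 of 31 were higher and 1 lower (27 and 1 when adjusted over the list alone; adjusted p = 2.47e-17; adjusted p = 0.0289 with an estimated correlation). Rec-1 had a median difference of -1.88 from SP-49 in this list, with 28 lower, also when adjusted over the list alone (adjusted p = 1.05e-18; adjusted p = 0.0379 with an estimated correlation). Of 16 Notch-linked B-cell genes, 13 were higher in SP-49 than in Mino, also when adjusted over the list alone, with a median of 1.93 (adjusted p = 3.97e-10; adjusted p = 0.0286 with an estimated correlation).

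The genes that set each line apart by the naming rule included HLA-DQA1 in Mino (7.66 ± 0.12, n = 2, against 1.61 in both other lines), CAV1 (7.55) and JCHAIN (9.74). In Rec-1 they included the kappa light chain gene IGKC (10.49 ± 0.11, n = 2), CRISP3 (8.57) and the collagenase MMP1 (7.85), and in SP-49 the scavenger receptor CD36 (9.05), PXDN (7.97) and the chemokine CCL22 (8.94). By limma, 5165 genes differed between Rec-1 and Mino, 5069 between SP-49 and Mino and 5714 between Rec-1 and SP-49. The serum level differed together with Mino, so a difference from Mino contains any effect of serum.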

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

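The tests of the spread between SP-49 replicates and of slower proliferation were chosen after the results they measure were seen, as were the fits without both doubted arrays and with array weights. The differences between lines listed here were picked out because the test of the difference itself, in limma, passed an adjusted p of 0.05.

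The inhibitor's effect differed between Rec-1 and Mino in 283 genes. The differences on the log2 scale were 2.39 for MTSS1, 2.36 for RNASE6, 2.25 for C16orf54, 2.22 for MARCHF1 and 2.11 for CD1C, and -3.73 for HES1, -3.39 for FCRL4, -3.36 for HEY1, -2.93 for CR2 and -2.74 for CXCL10. Between SP-49 and Mino, 9 genes differed, with 1.8 for BIK, -3.44 for HES1, -3.32 for FCRL4, -2.54 for CR2, -2.48 for CDK5R1 and -2.28 for CD300A. Between Rec-1 and SP-49, 110 genes differed, with 3.14 for CD1C, 2.55 for RNASE6, 2.53 for IFIT3, 2.49 for C16orf54 and 2.35 for DTNB-AS1, and -2.18 for SP3P, -1.99 for HEY1, -1.76 for KCNJ16, -1.67 for PYCR1 and -1.67 for KLHL21. HES1, FCRL4, CR2, HEY1, CXCL10, CDK5R1 and CD300A lay at or near the low end of the range in Mino without inhibitor, at 1.84, 1.82, 1.36, 2.39, 2.17, 2.17 and 2.35, which leaves little room for a measured fall, so their differences from Mino do not compare responses from like starting levels. The same limit holds for SP3P, KCNJ16 and HEY1 in SP-49, with mock levels of 1.24, 1.18 and 3.53, in the differences between Rec-1 and SP-49. Without 1 array, the calls of differences between Rec-1 and Mino ended for CXCL10 in 9 of 12 fits (adjusted p up to 0.136 without inhibitor replicate 1 of Mino), for MARCHF1 in 8 (up to 0.109 without mock replicate 2 of Rec-1), for C16orf54 in 5 (up to 0.11 without inhibitor replicate 1 of Mino) and for CD1C in 4 (up to 0.061 without inhibitor replicate 2 of Mino). Those between SP-49 and Mino ended for BIK and CD300A in 8 fits each (up to 0.166 without inhibitor replicate 1 of Mino and 0.235 without mock replicate 1 of SP-49). Between Rec-1 and SP-49, they ended for KLHL21 in 10 fits, C16orf54 in 8, HEY1 in 6 and SP3P in 5 (up to 0.161, 0.15, 0.0911 and 0.108, each without mock replicate 1 of SP-49), for PYCR1 in 5 and DTNB-AS1 in 2 (up to 0.107 and 0.0625 without mock replicate 2 of SP-49) and for RNASE6 in 2 (up to 0.0797 without mock replicate 1 of SP-49). The other differences listed passed without any 1 array. Among gene lists, 9 differed between Rec-1 and Mino, 6 between SP-49 and Mino and 12 between Rec-1 and SP-49, of which 4, 3 and 7 passed with an estimated correlation.

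The 13522 probe sets that name no single gene here were not used in the comparisons by gene. Tested with all probe sets, 205 of them passed in Rec-1, 62 higher and 143 lower, and 1, which was lower, passed in SP-49. In Mino 0 passed by limma. The test for outlying arrays within groups, which needs groups of at least 4 arrays, was not run. Inhibitor replicate 2 of Rec-1 stood apart from its replicate on the third principal component (35.4 against 6.17), and the counts without it and inhibitor replicate 2 of SP-49 are given with the other settings.

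More genes passed in Rec-1 (1141) than in SP-49 (38), although HES1 fell by 3.80 in Rec-1 and fell by 3.51 in SP-49. Both HES1 falls ended near the low end of the range, so their like size does not show a like response. A narrower signal range on inhibitor replicate 2 of Rec-1 is argued against as the whole cause, since 738 genes passed in Rec-1 without that array against 72 in SP-49 in the same fit. A larger spread between SP-49 replicates could not make the gap in the main fit, where both lines share 1 estimate of each gene's spread. The SD of the replicate difference was 0.274 in the inhibitor arrays of SP-49 and 0.372 in those of Rec-1 (0.206 and 0.253 in the mock arrays). In Rec-1 the shared estimate may therefore understate the error. With array weights the counts were 696 and 123, and with only each line's own 4 arrays 21 and 11, so the size of the gap depended on the fit. The fit of 4 arrays also has fewer degrees of freedom, and its effect was not told apart from that of the spread. A difference between the lines in how much of their expression depends on gamma-secretase may account for part of the gap, as a hypothesis drawn from these data and not tested. A difference between cultures that follows the line stays open, as no value here tests it. So does RNA quality, since the 3' to 5' difference of GAPDH was higher on both inhibitor arrays in Rec-1 and overlapped in SP-49. In Mino that of GAPDH was also higher with inhibitor (0.31 and 0.39 against 0.26 and 0.25), as was that of ACTB, yet 0 genes passed. In Rec-1 that of ACTB overlapped.

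Interferon-response genes rose in Rec-1, with a list median of 0.63. A rise on 1 array alone is argued against, since the smaller of the 2 inhibitor arrays' medians over the mock mean was 0.466 (the other 0.819), against a difference of 0.025 between the mock arrays. Compression of the signal range, which would raise all genes of like brightness, was tested with 10000 random lists matched on mean expression. The list's percentile was 100, and the central 95% of the random lists ran from -0.12 to 0.15. The matching used the mean over all arrays, but as a list interferon genes stood lower in Rec-1 than in SP-49 without inhibitor. The random lists may thus be brighter in Rec-1 than the interferon list, so the test cannot decide and compression stays open. A response to gamma-secretase inhibition in Rec-1 may account for the rise, but an effect of handling shared by both inhibitor cultures, such as cell density, was not tested and stays open, as does RNA quality, since the 3' to 5' difference of GAPDH was higher on both inhibitor arrays (0.59 and 0.49 against 0.41 and 0.37). The GAPDH difference was also higher with inhibitor in Mino, where 0 lists passed, and that of ACTB overlapped in Rec-1. CXCL10, which fell by 2.32, did not move with the rest of the list.

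Ribosome biogenesis genes fell in Rec-1 and as a list in SP-49, with medians of -0.94 and -0.41. Compression of the signal range is argued against by the list's percentile of 0 in both lines among 10000 random lists matched on mean expression, whose central 95% ran from -0.20 to 0.06 in Rec-1 and from -0.15 to -0.01 in SP-49. The matching used the mean over all arrays and not the level in each line, which limits this test. The lowest median of the G1/S and G2/M lists in these lines was -0.052. Slower proliferation stays open, since these lists bear on the share of cells in each phase and growth was not measured. A candidate explanation is the fall of MYC, which was lower in both lines by 1.54 and 1.55 in size and had a change of 0.13 in Mino, where the list median was 0.03. MYC was not changed on its own in these samples, so this stays a hypothesis, and RNA quality, untested here, stays open in Rec-1, where the 3' to 5' difference of GAPDH was higher with inhibitor. The GAPDH difference was also higher with inhibitor in Mino, where 0 lists passed, and that of ACTB overlapped in Rec-1.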

How the results depend on the processing

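Array weights and the fit without both doubted arrays were added after the data were seen. No called gene or list that is named changed its sign under any alternative, where a gene kept its chosen probe set unless its probe sets were averaged. A gene's other probe sets were not counted in this. The balance of higher and lower calls turned in several fits. In Rec-1 it went from 426 and 715 to 657 and 600 after quantile normalization, 372 and 366 without inhibitor replicate 2, 403 and 380 without both doubted arrays and 11 and 10 with only the arrays compared. For Rec-1 against Mino it went from 111 and 172 to 152 and 134 after quantile normalization, 124 and 109 without inhibitor replicate 2 of Rec-1 and 98 and 85 without both doubted arrays, and in the mock arrays from 2529 and 2636 to 2737 and 2646 after quantile normalization. For Rec-1 against SP-49 it went from 76 and 34 to 108 and 175 without inhibitor replicate 1 of Rec-1. Of the values of named genes under the alternatives, 3937 stayed on their side of the threshold, 365 lost and 34 gained a call, and of the list calls 392 stayed and 28 were lost. The replicate numbers were not taken to pair the arrays, by a rule that asked for r over 0.1 in every line (r of same-number differences 0.046, 0.094 and -0.011). The labels do not say what a number shares, so pairing is not excluded. With a replicate block the counts were 868 in Rec-1, 16 in SP-49, 219 on average, 105 for Rec-1 against Mino, 7 for SP-49 against Mino and 50 for Rec-1 against SP-49. With a trend and robust prior, counts were 1 in Mino, 1723 in Rec-1, 208 in SP-49, 886 on average, 730 for Rec-1 against Mino, 45 for SP-49 against Mino and 343 for Rec-1 against SP-49. Fitting only the arrays compared, which leaves fewer degrees of freedom by construction, gave 21 in Rec-1, 11 in SP-49, 70 for Rec-1 against Mino and 30 for Rec-1 against SP-49. Array weights gave 696 in Rec-1 and 123 in SP-49. Without both doubted arrays, counts were 13 in SP-49, 181 on average, 183 for Rec-1 against Mino and 38 for Rec-1 against SP-49. The mean of a gene's probe sets gave 60 in SP-49, and a minimum of 1.5-fold gave 95 on average. Testing every probe set, which tests more features by construction, gave 9194, 9291 and 10472 for the mock differences Rec-1 against Mino, SP-49 against Mino and Rec-1 against SP-49. With an estimated correlation, 6 lists passed in Rec-1 and 4 in SP-49. Correlations across genes were 0.02 (Rec-1 and Mino), -0.007 (SP-49 and Mino) and 0.187 (Rec-1 and SP-49) without both doubted arrays, and for SP-49 and Mino -0.063 with the mean of probe sets and -0.028 after quantile normalization. Except where construction is named, the cause was not tested. Leaving out 1 array at a time, counts ranged from 0 to 0 in Mino, 414 to 1997 in Rec-1, 7 to 72 in SP-49, 105 to 987 on average, 53 to 940 for Rec-1 against Mino, 4 to 13 for SP-49 against Mino and 6 to 283 for Rec-1 against SP-49. The mock differences ranged from 3933 to 5576, 3738 to 5553 and 4337 to 6175. Lists ranged from 0 to 3 in Mino, 11 to 14 in Rec-1 and 6 to 9 in SP-49, and correlations from -0.057 to 0.02 (Rec-1 and Mino), -0.063 to -0.007 (SP-49 and Mino) and 0.147 to 0.326 (Rec-1 and SP-49). Leaving out an inhibitor array of Rec-1 removes the pair with the largest replicate difference from the shared spread by construction. Signal near background limits falls that end there, such as HES1 in Rec-1 at 1.96.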

Other observations

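None of the tests in this part was chosen after its result was seen. Without inhibitor, SP-49 stood apart from Mino in activation genes. NF-kB targets, CCL22 among them, had a median difference of 1.46 (adjusted p = 0.0286 with an estimated correlation), immediate-early genes 0.77 (adjusted p = 0.0286 with an estimated correlation), B-cell receptor signalling genes 0.93 (adjusted p = 0.0472 with an estimated correlation) and chemokine and migration genes 0.77 (adjusted p = 0.0324 with an estimated correlation). Markers of mantle cell lymphoma were lower in Rec-1 than in Mino, with a median of -1.72 (adjusted p = 0.0407 with an estimated correlation), and lower than in SP-49, with a median of -0.97 (adjusted p = 0.0379 with an estimated correlation). Cholesterol genes were higher in Rec-1 than in Mino, with a median of 0.44 (adjusted p = 0.0407 with an estimated correlation). NOTCH1 was higher than in Mino in Rec-1 by 0.63 and in SP-49 by 1.32 (adjusted p = 0.00156 and 6.14e-06). CXCL10 was 18.8-fold higher in Rec-1 and 21.4-fold higher in SP-49 than in Mino, where it lay near the low end of the range (2.17), which limits how exactly these folds can be read.

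Other lists did not pass with the inhibitor. In Rec-1 and SP-49, the medians were -0.10 and 0.01 for Notch machinery, 0.18 and -0.11 for germinal centre genes, 0.18 and -0.11 for mantle cell lymphoma markers, -0.04 and 0.01 for apoptosis, 0.12 and -0.15 for p53 targets, 0.14 and -0.02 for MHC class II, and -0.02 and -0.06 for ATF4 stress. Ribosomal protein and cholesterol genes had medians of 0.03 and 0.18 in Rec-1 (adjusted p = 0.819 and 0.0779), and plasma-cell genes a median of -0.07 (adjusted p = 0.881), although JCHAIN, a member, rose by 1.56. The G1/S and G2/M lists had medians of -0.03 and 0.02 in SP-49, and B-cell receptor signalling, B-cell identity, NF-kB, immediate-early, chemokine and heat-shock genes did not pass there. The 6 lists of other cell types had medians from -0.04 to 0.09 in Mino (smallest adjusted p = 0.49). The median, the mean and the direction in camera differed in sign for 3 lists in Mino, 3 in Rec-1 and 8 in SP-49, and 0 of these passed in camera.

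The average over the lines was set against other divisions of the arrays within lines into groups of the same size. Of 100 divisions drawn from 108, the real one included, 5 gave as many genes as the real value of 376, and the highest other gave 491, so chance is not excluded by this count. The count does not bear on Rec-1 and SP-49, since the 4 other divisions with as many genes all kept the real division of these lines and divided Mino otherwise, where 0 genes passed, and the highest count among divisions that did not keep it was 26.

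A hypothesis was that the genes that fell in Rec-1 were already higher in SP-49 than in Mino without inhibitor, which would tie the shared response to a shared starting state. The 715 genes had a median difference of -0.35 between SP-49 and Mino in the mock arrays, 95 of them higher and 301 lower. Camera gave a shift down with p = 1.75e-08 at the preset correlation and p = 0.118 with an estimated correlation, so the hypothesis was not borne out.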
